A study of Mus musculus with 6 samples.

How the data were processed

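HMCP signal was analysed in 6 libraries from splenic B cells of C57BL/6J mice: 2 pull-down libraries and 1 input library from control cells (Dfl) and the same from cells lacking Tet2 and Tet3 (DKO). Groups and replicate numbers came from the sample titles. The authors deposited a table of RPKM values, reads scaled to region length and library depth, over 6864 regions with 2 decimals. The submitters' processing notes name Bowtie 1.1.2, SAMtools, Picard 2.7.1, MACS2 and HOMER, and the builds mm10 and GRCm38, without saying which tool made which step. How the regions were called, how duplicates and reads with several matches were treated, and how reads were assigned to regions are not given in the sources used here. The values were not divided by input, and no spike-in was used here, so a pull-down that worked less well in a library would lower its values at every enriched region.

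Depth was recovered from the RPKM values. In each library the depth was found at which RPKM multiplied by region length and depth gave whole reads, within the rounding of 2 decimals, and this held for 100% of the low values tested, against 4.4% to 9.66% by chance. The depths were 6437000 and 10261000 reads (Dfl pull-downs), 5212000 and 7524000 (DKO pull-downs), 18506000 (Dfl input) and 22115000 (DKO input). The regions held 28794 and 54388 reads of the Dfl pull-downs, 21688 and 18903 of the DKO pull-downs, and 55290 and 103893 of the inputs. At 1 or 2 reads in a median region, the values of single regions rest mainly on counting error. Signal over a set of regions was computed as reads summed over the set, divided by total length and depth. Intervals of read ratios are exact 95% intervals from the binomial distribution; these and the limit of 3 reads for a count of 0 cover counting error only, because reads are not independent molecules.

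Differences per region were tested on log2(RPKM + 0.1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A fold change on this scale understates the change of low regions. The fit fixed before the data were examined used the 4 pull-down libraries and all regions but the 185 at 0 in every pull-down. Because that fit could not recover large simulated changes, a second fit was added after seeing the data with a minimum of 20 reads summed over the 4 pull-downs. Reads are summed over more depth in Dfl than in DKO, so the minimum was also applied to reads counted at 1 depth. Both fits were tested on simulated libraries with the real depths and mean signals and an overdispersion of 0.038. Pull-down and input were compared in a limma fit of all 6 libraries. Region sets were tested with camera (correlation 0.01, and again with an estimated correlation) and fry, two-sided, adjusted over the sets of a family. Library levels were compared with exact permutation tests. Summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

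Regions were annotated with NCBI RefSeq genes of the same build. The annotation used here gives gene ends but neither strand nor exons, so the planned promoter class was replaced by regions within 1000 bp of either end of a protein-coding gene. Other regions lay inside a protein-coding gene or were called intergenic, and exons and introns were not told apart. Regions at 3 RPKM or more in either input were set apart as regions of high input (161 regions, 1.62% of the length); they held between 27.6% and 41.4% of the pull-down reads in regions. The 17 gene lists were fixed before the data were examined: B cell identity, germinal centre, AID targets and translocation partners, G-quadruplex oncogene promoters, DNA methylation, R-loop and G-quadruplex resolution, DNA damage response, immediate early, immunoglobulin constant, cell cycle and MYC, T cell, myeloid, plasma cell, erythroid, housekeeping, ribosomal protein and histone genes. A list took the regions within a gene or 1000 bp beyond its ends, and was tested with at least 5 regions.

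The named regions followed a rule set before the data were examined. Among regions at or above the median pull-down RPKM, it took the 10 largest falls and rises past the threshold with both DKO libraries on the same side of both Dfl libraries, or, where fewer passed, up to 5 such regions per direction named as not past it. It also took the region with the highest mean pull-down RPKM for each of Cd19, Pax5, Ebf1, Cd79a, Bcl6, Aicda, Myc, Bach2, Ighm and Dnmt1. The 20 largest falls and the 5 rises with at least 20 reads, and regions named for their gene, were added after their values were seen.

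Alternatives covered the pseudocount (0.01 and 1), minimum signal, library centring and quantile normalization, division by input, a replicate block, a fit without trend, leaving out each library, and the set tests. Replicates were compared before averaging: over regions with at least 20 reads, chi-square per degree of freedom was 2.26 for the Dfl pair and 1.17 for the DKO pair (p = 1.55e-94 and 1.57e-04), so neither pair agreed within sampling noise. Spearman correlations over these regions, which are not independent, were 0.866 for the Dfl pair and 0.522 for the DKO pair.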

Results

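5-hydroxymethylcytosine (5hmC), the oxidised form of methylated cytosine that TET enzymes make, was mapped in splenic B cells of C57BL/6J mice aged 10 weeks by HMCP, a pull-down that enriches DNA fragments carrying 5hmC before sequencing. Sorted YFP-positive B cells lacking Tet2 and Tet3 in the CD19 lineage (DKO) were compared with CD19-positive, YFP-negative control B cells (genotype Dfl). Each genotype had 2 pull-down libraries and 1 input library of genomic DNA that had not been pulled down. The signal was given as RPKM over 6864 regions, the union of G-quadruplex and R-loop regions of the study, with a median length of 486 bp (124 to 12483 bp) and on build GRCm38. The step size of the RPKM values gave depths of 6437000 and 10261000 reads for the Dfl pull-downs, 5212000 and 7524000 reads for the DKO pull-downs, and 18506000 and 22115000 reads for the Dfl and DKO inputs. These depths put a median of 1 or 2 reads per region in each pull-down library, and between 23.0% and 33.5% of regions stood at 0. A single read in a region of median length was worth 0.201 to 0.395 RPKM, and 3 reads, taken as the limit that a count of 0 allows, were worth 0.602 to 1.18 RPKM. Nothing in the labels says that the replicates came from separate animals, so the p-values rest on the spread between these libraries, which may be technical. That spread was pooled by limma over regions, in part or wholly.

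The first question was whether the pull-down recovered DNA above the input, and so how much 5hmC signal these regions held in each genotype. In control B cells, 106 of the 953 regions with at least 20 reads over the 4 pull-down libraries stood above the input and 0 below it, whereas in DKO cells 0 stood above the input and 2 below it. Over all regions, the summed signal was 0.926 ± 0.111 RPKM in Dfl (SD, n = 2), 1.64 times that of its input, and 0.632 ± 0.221 RPKM in DKO (SD, n = 2), 0.71 times that of its input. The Dfl libraries stood at 1.5 and 1.77 times their input and the DKO libraries at 0.886 and 0.535 times theirs. Without the 161 regions of high input (3 RPKM or more in either input), the Dfl libraries had 0.505 and 0.672 RPKM (1.15 and 1.53 times input) and the DKO libraries 0.570 and 0.351 RPKM (0.77 and 0.474 times input). The calls came from limma on all 6 libraries, in which the lone input of each genotype was assumed to vary like the other groups, with a Benjamini-Hochberg adjusted p under 0.05. In DKO, 6 regions stood above input at an unadjusted p under 0.05. The minimum of 20 reads was chosen after seeing the data, and without it 5 regions stood above and 156 below the input in Dfl, and 0 above and 178 below in DKO. The pull-downs stood at 0 in 23.0% to 33.5% of regions, and the deeper inputs in 4.6% (Dfl) and 0.7% (DKO). Calls below input over all regions are therefore no measure of depletion. The minimum of 20 reads counts pull-down reads and not input reads, and most came from Dfl (21946 and 43205 in Dfl, 11929 and 10596 in DKO). It therefore favours regions with the Dfl pull-down above input. Calls in Dfl and not in DKO are no test of a difference between them. The direct test, given further on, called 24 regions lower and 0 higher in DKO.

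Most regions held too little signal to follow singly. The median log2 ratio of pull-down to input over all regions was -0.55 in Dfl (-0.39 and -0.37 in its libraries) and -0.91 in DKO (-0.45 and -1.07 in its libraries), on the log2(RPKM + 0.1) scale. With pseudocounts of 0.01 and 1 the medians were -0.96 and -0.12 in Dfl, and -1.25 and -0.31 in DKO. Their size thus depends on the many values at or near 0. With at least 20 reads the median log2 ratio was 0.65 in Dfl and -0.40 in DKO. The inputs themselves differed: the DKO input was 1.57 times the Dfl input over the summed regions, and the median log2 difference was 0.66, with no replicate of either input to test it.

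**Figure D1:**
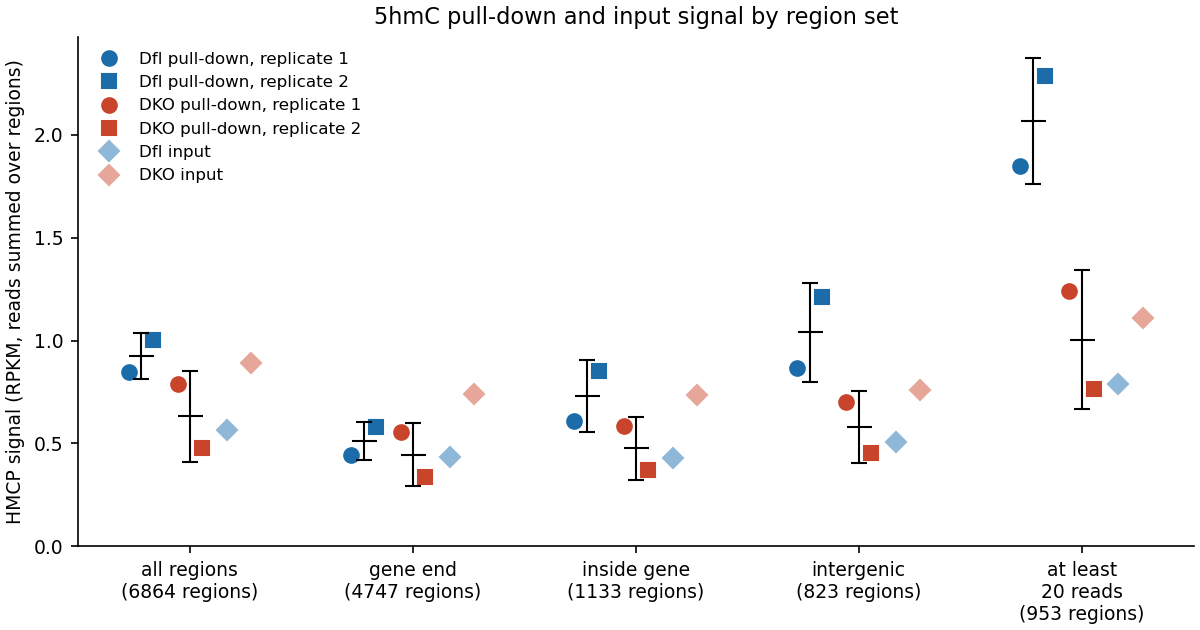
Signal in RPKM (y axis, reads summed over the regions of a set) of each pull-down and input library, for all regions, for regions at a gene end, inside a gene or between genes (these 3 without regions of high input), and for regions with at least 20 reads; black bars give the mean and SD of the 2 pull-downs of a genotype. With at least 20 reads the Dfl pull-downs stand at 1.85 and 2.28 RPKM and the DKO pull-downs at 1.24 and 0.764 RPKM, beside inputs of 0.787 and 1.11 RPKM.

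The central comparison asked whether loss of Tet2 and Tet3 changed 5hmC signal over G-quadruplex and R-loop regions. The clearest difference was a lower signal in DKO cells at a subset of well-covered regions. Among the 953 regions with at least 20 reads, 139 (14.6%) were lower and 5 higher in DKO, and 137 of the 139 had both DKO libraries below both Dfl libraries. Selection of the 139 in the same libraries largely fixed this separation, so it adds no support. The summed signal of the 139 regions was 9.06 ± 1.11 RPKM in Dfl and 2.06 ± 0.682 RPKM in DKO (SD, n = 2 each), 4.41-fold apart. In Dfl this was 7.08 and 8.42 times the input, and in DKO 1.64 and 1.01 times. These levels were set largely by 17 regions of a stretch on chromosome 6, described further on. The other 122 regions had 3.82 ± 1.36 RPKM in Dfl and 0.622 ± 0.159 RPKM in DKO, 6.14-fold apart, at 6.29 and 10.5 times the input in Dfl and 1.04 and 0.719 times in DKO. The median log2 difference over the 139 regions was -2.38, ranging from -6.09 to -1.56; these regions were selected for the difference, so its size is not an unbiased estimate.

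The 139 regions came from limma with a trend on log2(RPKM + 0.1) and a minimum of 20 reads chosen after seeing the data. In that fit the prior degrees of freedom were infinite, so the spread came wholly from the trend over regions. The replicate spread of a single region had no weight in its p-value. The test fixed before the data were examined, limma over all 6679 regions with signal in any pull-down, gave 0 lower and 0 higher regions (smallest adjusted p = 0.265), with 333 lower and 294 higher at an unadjusted p under 0.05. In simulated libraries of these depths that test recovered 0% of 8-fold changes. With at least 20 reads limma recovered 0% of 2-fold, 41.2% of 4-fold and 73.5% of 8-fold simulated changes. These are shares of the changed regions that kept 20 reads (145, 119 and 113 of 200). Changes were made by lowering the pooled mean signal in 1 genotype, in 1 run per fold. So this fit did not detect 2-fold differences in these simulated libraries. False calls numbered 0 when nothing had changed, 3 in the 4-fold run and 1 in the 8-fold run. Both genotypes were simulated with the same overdispersion, and whether the real replicates share it was not tested. Chi-square per degree of freedom was 2.26 for the Dfl pair and 1.17 for the DKO pair. That value grows with read number, which was larger in Dfl, so it does not rank the pairs. The simulation therefore cannot vouch for the number of false calls in the real data. The number of lower regions was 65 without Dfl replicate 1, 26 without Dfl replicate 2, 66 without DKO replicate 1 and 42 without DKO replicate 2.

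Some of the lower regions lay in or next to genes with known functions in immune cells. At the end of Ptpn6, which encodes the inhibitory phosphatase SHP-1, the region at chromosome 6, 124720996 to 124721679, had 21.5 ± 11.8 RPKM in Dfl and 1.66 ± 0.424 in DKO (limma, log2 difference -3.53, SE 0.703, adjusted p = 2.69e-05). Inside Ccr7, the chemokine receptor that guides lymphocytes to lymphoid tissue, the region at chromosome 11, 99150032 to 99150514, had 5.74 ± 1.30 RPKM in Dfl and 0.34 ± 0.085 in DKO (log2 difference -3.73, adjusted p = 2.64e-05). The region of 8516 bp at Klf2 (chromosome 8, 72317410 to 72325925), a transcription factor of lymphocyte quiescence and trafficking, had 7.47 ± 2.46 RPKM in Dfl and 1.29 ± 0.247 in DKO (adjusted p = 0.013). At Pold1, the catalytic subunit of DNA polymerase delta, the region at chromosome 7, 44533234 to 44535038, had 16.3 ± 6.42 RPKM in Dfl and 2.57 ± 0.325 in DKO (adjusted p = 0.00383). Irak2, a kinase of Toll-like receptor signalling, had 6.30 ± 2.63 and 0.665 ± 0.375 RPKM. Tfeb, a transcription factor of lysosomal genes, had 5.07 ± 1.46 and 0.97 ± 0.17 RPKM. Bcl2l1, which encodes the survival protein BCL-XL, had 2.26 ± 0.778 and 0.315 ± 0.106 RPKM. All means are ± SD with n = 2. Ptpn6, Pold1, Irak2 and Tfeb were chosen after their values were seen. Ccr7, Klf2 and Bcl2l1 belong to gene lists fixed in advance, but were named because their regions were called. No enrichment of immune genes among the called regions was tested. Of the 14 gene lists tested with camera over all regions, B cell identity, germinal centre and plasma cell genes included, none passed (adjusted p of 0.471 to 0.969).

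Of the 12 regions with at least 20 reads in, at the end of or nearest to an H2 gene or Tapbp, genes that serve the display of peptides to T cells, 5 were lower in DKO and 7 were not called (adjusted p of 0.107 to 0.635). This group was chosen after its values were seen, and no enrichment was tested. The region at the class II gene H2-Eb1 (34304389 to 34306843) had 2.53 ± 0.70 RPKM in Dfl and 0.505 ± 0.177 in DKO, and the intergenic region 4425 bp from that gene (34301202 to 34301442) had 15.95 ± 4.33 and 1.23 ± 0.601 RPKM. At the class I genes H2-Q6 and H2-Q7 the values were 6.20 ± 2.77 against 1.29 ± 0.389 RPKM and 4.54 ± 1.51 against 0.425 ± 0.601 RPKM. A region shared by Tapbp, which loads class I molecules with peptide, and Zbtb22 had 7.01 ± 2.71 RPKM in Dfl and 1.06 ± 0.651 in DKO. These 5 regions passed limma's adjusted threshold, with adjusted p between 4.67e-06 and 0.0318. H2-Q6 and H2-Q7 are close relatives, and reads that fit both could not be told apart here.

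**Figure D2:**
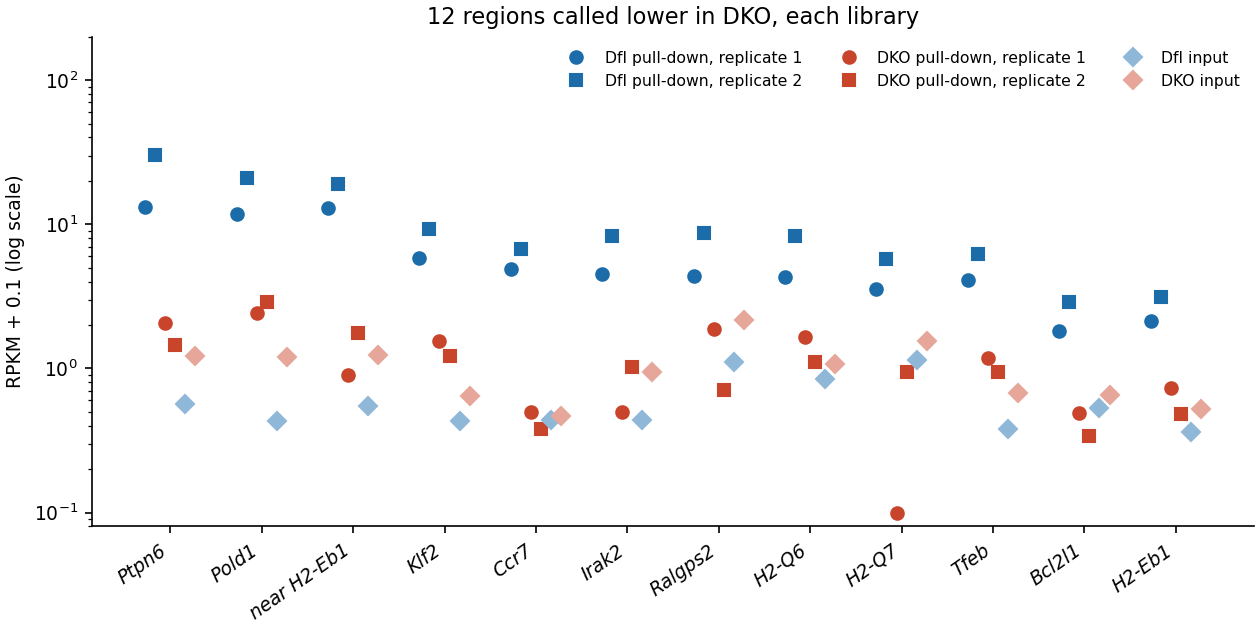
Signal in RPKM + 0.1 (log axis) of the 4 pull-down and 2 input libraries at 12 regions lower in DKO, named by the gene they lie in or next to, with each point a library. Both Dfl pull-downs lie above both DKO pull-downs at all 12 regions, with 13.2 and 29.9 RPKM against 1.96 and 1.36 RPKM at Ptpn6, for example, and 1.71 and 2.81 RPKM against 0.39 and 0.24 RPKM at Bcl2l1. The choice of regions lower in DKO largely fixed this separation.

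The rule for named regions, set before the data were examined, took the largest changes over all regions, none of which passed the adjusted threshold there. The 5 largest falls were at regions with 0 reads in both DKO libraries. The largest was in the lncRNA gene Gm32605, outside protein-coding genes (chromosome 10, 117910509 to 117910824; 49 reads in Dfl, at least 12.5-fold lower in DKO). The next was inside Jade2 (chromosome 11, 51843199 to 51843450; 16 reads, at least 4.07-fold lower). The others lay at the ends of Nkiras2 and Zfp385c (chromosome 11, 100626728 to 100627165; 23 reads, at least 5.85-fold), Fam32a (chromosome 8, 72219594 to 72219884; 19 reads, at least 4.83-fold), and 1894 bp from Fgd2 (chromosome 17, 29381429 to 29381847; 25 reads, at least 6.36-fold). These folds set the Dfl reads against 3 reads over the 2 DKO libraries and leave out the counting error of the Dfl reads. With that error included, the exact 95% lower bounds were 9.75-fold (Gm32605), 2.94-fold (Jade2), 4.38-fold (Nkiras2), 3.56-fold (Fam32a) and 4.80-fold (Fgd2). Adjusted p in the test of all regions lay between 0.265 and 0.354 for these 5, and the regions of Gm32605, Nkiras2 and Fgd2 were among the 139 with at least 20 reads. The 5 largest rises, at the ends of Tm9sf2, Tatdn1 and Ndufb9, Smad5, Sf3b5, and Map11, rested on 4 to 7 DKO reads against 0 Dfl reads, with adjusted p of 0.354 to 0.356.

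Beyond those, the strongest falls among regions with at least 20 reads lay inside Hs1bp3 (37 reads in Dfl against 1 in DKO), Rinl (56 against 4), Ptpn14 (31 against 1), Zfp362 (30 against 3), Mtss1 (97 against 5), Pde7b (48 against 4) and Amz1 (117 against 7). Falls at gene ends were found at Pdlim2 (19 against 2 reads) and Csgalnact2 (39 against 2 reads), and others lay between genes, 45890 bp from Ets1 (28 against 0 reads), 12243 bp from Proser2 (57 against 3), 9429 bp from Oxa1l (85 against 2), 52001 bp from Ccdc167 (26 against 1) and 4801 bp from Mrps23 (70 against 3). The 5 regions higher in DKO had low signal in 4 cases, at Add3 (0.11 ± 0.014 RPKM in Dfl, 0.535 ± 0.346 in DKO), Psme3ip1 and Rspry1, Ubald1, and Tef (0.145 ± 0.092 and 0.745 ± 0.247 RPKM). The other rise was at chromosome 9, 87839551 to 87839743, between genes, with 4.02 and 0.50 RPKM in Dfl and 7.95 and 7.58 RPKM in DKO (adjusted p = 0.0172). In the 4 cases of low signal the DKO pull-downs did not stand clearly above their input. They had 0.78 and 0.29 RPKM against 0.80 at Add3, 0.67 and 0.46 against 0.89 at Psme3ip1, 0.81 and 0.50 against 0.61 at Ubald1, and 0.92 and 0.57 against 0.82 at Tef. These regions were chosen as the 20 largest falls and the 5 rises after the minimum of 20 reads had been set.

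**Figure D3:**
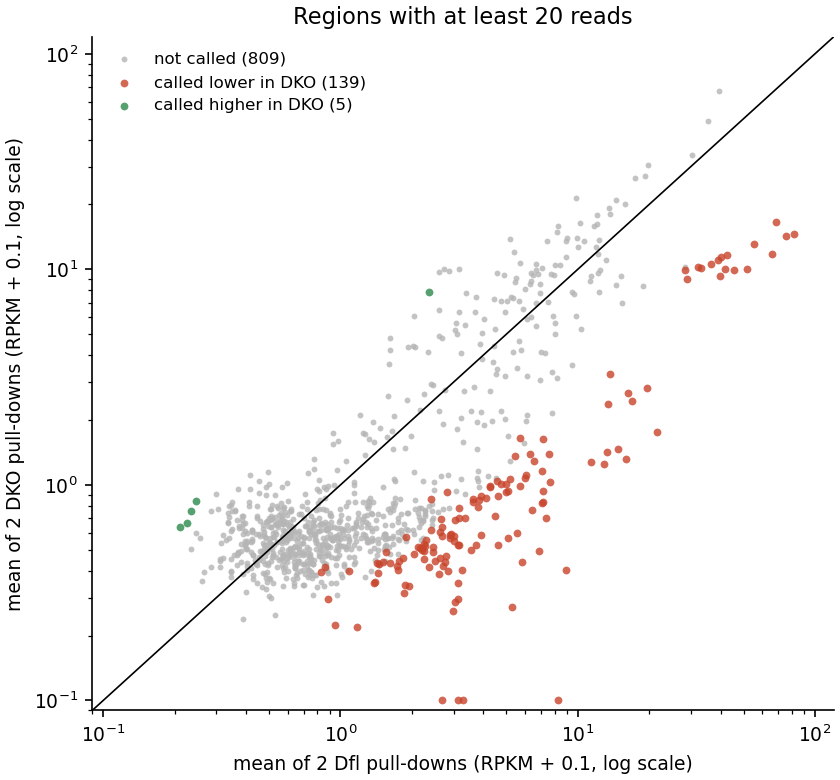
Mean signal of the 2 DKO pull-downs (y axis) against that of the 2 Dfl pull-downs (x axis), both in RPKM + 0.1 on log axes, for each of the 953 regions with at least 20 reads, with the line of equal signal. The 139 regions lower in DKO fall below the line at Dfl means of 0.725 RPKM and above, and the 5 higher regions lie above it.

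The densest group of lower regions lay on chromosome 6, between 47651630 and 47778312, where 17 of 19 regions in 126.7 kb were lower in DKO. This stretch holds 6 predicted protein-coding genes (among them Gm40363, Gm40365 and Gm40369), 2 lncRNA genes and the 4.5S RNA gene Rn4.5s. The 17 regions had 40.3 ± 0.332 RPKM in Dfl and 10.6 ± 3.80 RPKM in DKO (SD, n = 2 each), 7.43 and 1.61 times their inputs. Their inputs were high too, at 5.43 and 6.57 RPKM, and near-identical copies could share these reads. Without this stretch, 118 regions were lower. On chromosome Y, 4 regions between 90742082 and 90772923 were lower as well, with 13.8 ± 1.45 RPKM in Dfl and 1.88 ± 0.98 in DKO. So were 2 regions on chromosome X at and next to Mid1 (169991038 to 169991537, 13.6 ± 2.54 and 3.16 ± 2.59 RPKM; 169997806 to 169998444, 19.45 ± 3.78 and 2.71 ± 2.96 RPKM). These 6 regions lie in or near the pseudoautosomal stretch that X and Y share, so their reads could not be assigned to either chromosome with certainty.

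**Figure D4:**
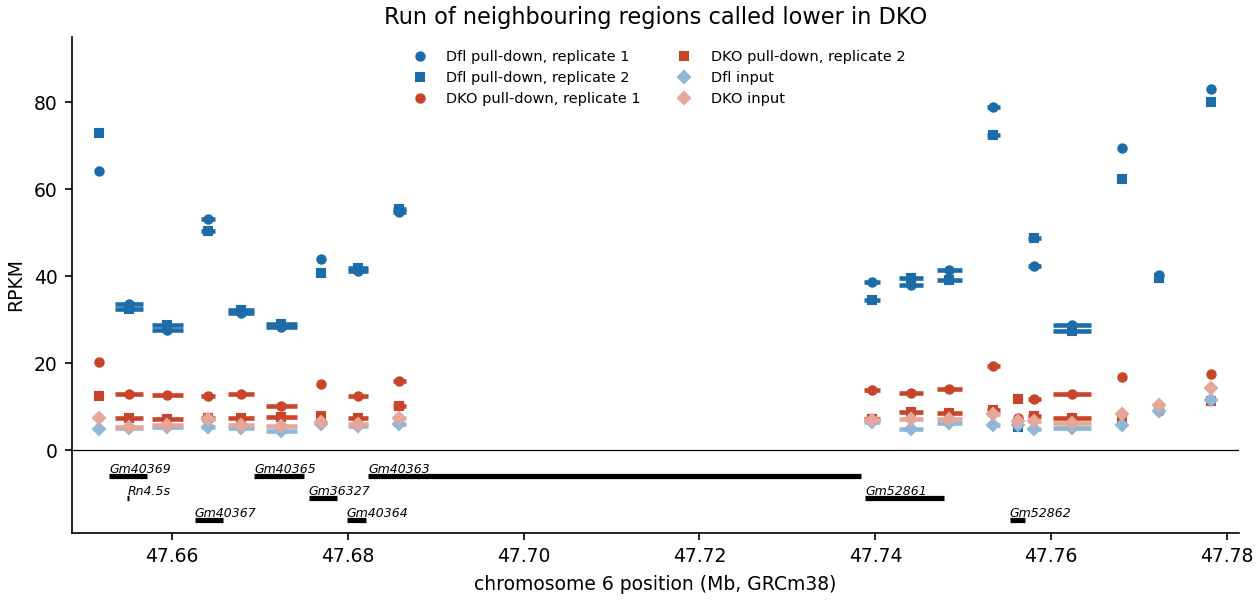
Signal in RPKM (y axis) of each library at 19 neighbouring regions along chromosome 6 (x axis in Mb, GRCm38), each drawn over its own length with a marker at its middle, and annotated genes as black bars below. The 17 lower regions range from 27.7 to 82.89 RPKM in the Dfl pull-downs and from 6.59 to 20.36 RPKM in the DKO pull-downs.

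Regions were then compared by their place relative to genes. Of the regions with at least 20 reads, 48 of 186 inside a protein-coding gene were lower in DKO (25.8%), as were 45 of 208 between genes (21.6%) and 46 of 559 within 1 kb of a gene end (8.2%). Summed over all regions of a class without those of high input, the Dfl libraries had 0.445 and 0.578 RPKM at gene ends and the DKO libraries 0.553 and 0.336 RPKM, so the genotypes overlapped there and the ratio of their means, 1.15-fold, has no clear direction. The Dfl signal was 1.54-fold that of DKO inside genes (0.608 and 0.854 against 0.584 and 0.368 RPKM) and 1.80-fold between genes (0.867 and 1.21 against 0.702 and 0.454 RPKM). In the same sets the Dfl pull-down was 1.177 times its input at gene ends, 1.696 times inside genes and 2.055 times between genes. Gene ends thus had less signal above input that could fall, and their smaller share of lower regions does not show that they were spared. Regions are not independent replicates, and limma's camera test of the classes at this depth gave an adjusted p of 0.0749 for gene ends and for regions inside genes, and of 0.689 for regions between genes. Over all 6679 regions, camera placed gene ends above and intergenic regions below the rest (adjusted p = 0.00903 each), with median log2 differences of 0.32 and -0.01; neither held with an estimated correlation (adjusted p = 0.648). For gene ends the positive median was -0.40 after division by input and 0.06 without DKO replicate 1. Regions inside genes (adjusted p = 0.0664) and those on chromosome X (adjusted p = 0.191) did not pass. Regions inside genes did pass camera at a mean of at least 0.5 RPKM (adjusted p = 0.0452) and with gene ends widened to 2 kb (0.0257). Neither held with an estimated correlation (0.736 and 0.574). Intergenic regions did not pass camera at a mean of at least 0.5 RPKM (adjusted p = 0.149).

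Of the B cell identity genes, 24 regions were measured and 8 had at least 20 reads, of which 2 were lower in DKO, at H2-Eb1 and at Ralgps2 (6.42 ± 2.99 RPKM in Dfl, 1.19 ± 0.82 in DKO). Among targets of the deaminase AID and translocation partners, Ccr7 was lower, 1 of 4 regions with at least 20 reads. Klf2 was lower among immediate early genes, 1 of 8. Bcl2l1 gave the 1 lower region of 2 in the germinal centre list and the 1 of 1 in the erythroid list, which share it. No region with at least 20 reads was called among DNA methylation genes (3 regions), genes resolving R-loops and G-quadruplexes (4), DNA damage response (3), cell cycle and MYC genes (4), plasma cell (4), housekeeping (6), ribosomal protein (2), histone (2), myeloid (2) or G-quadruplex oncogene promoters (2). T cell genes had 2 regions, none with 20 reads, and immunoglobulin constant genes had 0 regions. None of the 14 lists with at least 5 regions passed camera over all regions (adjusted p of 0.471 to 0.969), and none held a region past the threshold over all regions tested. The camera direction was down but the mean log2 difference positive in the DNA methylation list (median -0.33, mean 0.004), the G-quadruplex oncogene list (median -0.23, mean 0.03), the erythroid list (median 0.19, mean 0.04) and the housekeeping list (median 0.24, mean 0.10), since the median limma difference over all regions tested was itself 0.24. Adjusted over the list alone, 1 region was lower in the AID target list, 1 lower in the erythroid list and 1 higher in the cell cycle and MYC list.

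Of the genes named in advance, Pax5, Ebf1, Cd79a, Bach2 and Dnmt1 had regions, and the region taken for each did not pass. Bach2, a repressor of plasma cell differentiation, had 1.12 and 2.26 RPKM in Dfl and 0.56 and 0.96 RPKM in DKO, a 2.29-fold ratio of reads with an exact 95% interval of 0.94 to 6.37 (adjusted p = 0.737 in limma over all regions and 0.368 with at least 20 reads). The regions of highest mean pull-down RPKM at Pax5, Ebf1, Cd79a and Dnmt1 held at most 6 reads in either genotype. Cd19, Bcl6, Aicda, Myc and Ighm had no region. The deleted genes had 1 region each, at the end of Tet2 (0.39 and 0.49 RPKM in Dfl, 0.48 and 0 in DKO) and of Tet3 (0.66 and 0.31 RPKM in Dfl, 0.20 and 0.56 in DKO). Whether either lies in the deleted part is not given in the sources used here, so they do not check the genotype.

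The overall level gave no single direction. The median RPKM over regions was higher in DKO, with 0.31 and 0.315 in the Dfl libraries and 0.53 and 0.32 in the DKO libraries. The summed signal was lower in DKO, with 0.848 and 1.004 RPKM in Dfl and 0.788 and 0.476 RPKM in DKO. The libraries of the genotypes did not overlap on either measure, but without regions of high input the summed signals did, with 0.505 and 0.672 RPKM in Dfl and 0.570 and 0.351 RPKM in DKO. For the median, 0.315 in Dfl and 0.32 in DKO differ by far less than 1 read in a median region is worth. The higher median in DKO thus rests on DKO replicate 1. Over all regions the exact permutation test gave p = 0.33 for both, the smallest possible with 2 libraries against 2, so it could not pass the threshold. The median log2 ratio of the genotype means (RPKM + 0.1) was 0.27 and turned to -0.067 without DKO replicate 1. Over all regions, 978 (14.25%) had both DKO libraries below both Dfl libraries and 1343 (19.57%) the reverse, where chance gives 16.7% each without ties. Values tied at 0 are common, with 23.0% to 33.5% of regions at 0 in a pull-down, and they lower that share. With at least 20 reads, 433 (45.44%) were lower and 115 (12.07%) higher. Centring each library on its median changed the shares over all regions to 23.14% and 15.66%, and dividing by the input to 33.39% and 13.69%. After division both pull-downs of a genotype share 1 input, and the inputs differed. The chance share of 16.7% therefore does not hold for the divided values.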

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

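The test of input difference was chosen after the result was seen, as were the minimum of 20 reads and the test of loss of 5hmC. The difference between genotypes in pull-down over input was tested as an interaction in limma over all 6 libraries. With at least 20 reads, 24 regions had a lower pull-down over input in DKO than in Dfl and 0 a higher ratio. Over all regions, 70 had a lower and 19 a higher ratio in DKO. With 1 input library per genotype, these calls assume that the inputs vary like the pull-downs.

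The pattern weighed is the lower DKO signal at 139 regions with at least 20 reads. A large enough loss of the underlying DNA was not seen in the inputs: over these regions the median input log2 difference, DKO minus Dfl, was 0.40 (quartiles 0.17 and 0.89). A cause in copy number or mapping needs -1 or less. The DKO input was also higher over all regions (median 0.66), so the positive value here is no sign of a change in the other direction. Smaller depth in DKO stays open for the number of regions called: with all pull-downs thinned to 5212000 reads it fell to a median of 35.5 over 20 draws (0 to 123). Fewer reads were left, and the prior degrees of freedom of the spread fell from infinite to a median of 6.11. The draws had a median of 0 higher regions (at most 3). At a limma adjusted p under 0.1 they had a median of 116 lower regions (53 to 176). The median log2 difference over the 139 regions was -2.38 before (quartiles -3.07 and -2.10) and -2.40 after (quartiles -3.06 and -2.06), as thinning leaves the expected ratio of RPKM unchanged. Loss of 5hmC with Tet2 and Tet3 deletion, the biological candidate, would put both DKO libraries under 1.5 times their input: they stood at 1.64 and 1.01 over all 139 regions and at 1.04 and 0.719 over the 122 outside the chromosome 6 stretch, which does not settle it, since the regions were chosen for a low DKO signal and the 122 were set apart after their values were seen. A weaker pull-down in both DKO libraries would also bring the signal near input, and it cannot be told apart from a loss of 5hmC, since pull-down and genotype change together without a spike-in: the 9 regions at least 2-fold over input in DKO replicate 1 stood at 1.61 times input in DKO replicate 2, between the bounds set for either outcome.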

How the results depend on the processing

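The settings that require 20, 10 or 40 reads, leave out regions of high input or the chromosome 6 stretch, count reads at 1 depth or use voom weights were added after seeing the data. The count tests planned for reads, the window at the transcription start only, and the classes by CpG content and G-quadruplex motif were not run, as the unit was RPKM and neither strand nor genome sequence was used here. Over all regions limma gave 0 lower and 0 higher regions, also with other pseudocounts, centring, quantile normalization, division by input, all 6 libraries, no trend and without each library. It gave 9 lower regions at a mean of at least 0.5 RPKM, 76 lower and 4 higher at pull-down over input of at least 1.5, 139 lower and 5 higher with at least 20 reads, 53 and 2 with at least 10, and 136 and 1 with at least 40; fewer regions near 0 were tested in each, and of the last 136, 99 were among the 139. The replicate numbers share only a number (correlation of deviations 0.025): with the replicate block 68 regions were lower and 28 higher over all regions, and 68 lower and 3 higher with at least 20 reads, which left 1 residual degree of freedom, and the block changed no set test. With at least 20 reads, the lower regions numbered 26 to 66 and the higher 1 to 4 without each library, where the lone library is assumed to vary like the other group. Centred on the median of all regions, which moved limma's median log2 difference from -0.54 to -0.86, 207 were lower and 2 higher, 129 of them among the 139. Divided by input, 354 were lower and 4 higher (134 shared), with voom weights 143 and 4 (84 shared), without high input 115 and 4, counted at 1 depth 123 and 4, and without the chromosome 6 stretch 118 and 5. Division used the same input for both pull-downs of a genotype, so the error of that input did not enter the spread. The 354 calls are therefore too many to trust. The interaction over all 6 libraries, which includes that error, called 24 regions lower and 0 higher. All 139 kept a negative difference in each setting that tested them. Their selection for a lower DKO signal in the same 4 libraries largely fixed this, so it is no sign of robustness. The median log2 ratio of genotype means, 0.27 (limma's median difference of mean logs was 0.24), became -0.43 divided by input and -0.50 with at least 20 reads, where limma's was -0.54, and ranged from -0.067 to 0.37 without each library. The share of regions lower in DKO, 14.25%, became 26.01% at a mean of at least 0.5 RPKM, 23.14% centred, 33.39% divided by input and 45.44% with at least 20 reads. It was 18.82% to 29.94% without each library, where chance gives 33.3% if no values are tied. The share higher, 19.57%, was 28.35% to 48.3% without each library, highest without DKO replicate 2. The median log2 ratio to input in Dfl, -0.55, became -0.96 and -0.12 with pseudocounts of 0.01 and 1, -0.62 at an input of at least 0.1 RPKM, 0.65 with at least 20 reads, and -0.39 to -0.37 with a single library. In DKO, -0.91 became -0.31 with a pseudocount of 1, -0.40 with at least 20 reads, and -1.07 to -0.45 with a single library. The input difference of 0.66 became 0.74 and 0.29 with pseudocounts of 0.01 and 1. Of the region classes, 2 passed camera, and 0 with an estimated correlation, with fry, divided by input or with at least 20 reads, and 0 to 3 without each library. No gene list passed in any setting run. Except where fewer regions or libraries entered, the cause was not tested. Depth limits most regions: a median region holds 1 or 2 reads per pull-down.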

Other observations

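Regions chosen in a single library gave a view of the 5hmC signal that does not depend on the comparison of genotypes; this test was set before its result was seen. At the 66 regions with at least 10 reads and at least 4-fold over input in Dfl replicate 1, without regions of high input, Dfl replicate 2 stood at 6.10 RPKM and the DKO libraries at 0.977 and 0.715 RPKM. At the 216 regions chosen in the same way in Dfl replicate 2, Dfl replicate 1 stood at 2.11 RPKM and the DKO libraries at 0.746 and 0.527 RPKM. The other Dfl library was therefore 6.24 and 2.83 times the higher DKO library, where chance peaks of a single library would give no excess. The same choice found 0 regions in DKO replicate 1 and 1 in DKO replicate 2, the region on chromosome 9 between genes that was also higher in DKO. The numbers of regions chosen are not on an equal footing. Depth differed between libraries, and the DKO input was 1.68 times the Dfl input over the regions without high input.

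The DKO pull-downs correlated in rank order with every other library to a similar degree. Over the 953 regions with at least 20 reads, which are not independent replicates, Spearman's correlation was 0.522 between the DKO pull-downs, and 0.50 and 0.522 between each of them and the DKO input, 0.477 and 0.463 between each of them and the Dfl input, and 0.482 to 0.551 between a DKO and a Dfl pull-down. It was 0.866 between the Dfl pull-downs, and 0.461 and 0.404 between each of them and the Dfl input.

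Other lower regions lay in or near immune genes and were chosen after their values were seen. A region 12776 bp from Icosl, the ligand of the T cell costimulator ICOS, had 14.6 ± 3.90 RPKM in Dfl and 1.37 ± 0.488 in DKO. Others lay 9251 bp from Syk, a kinase of B cell receptor signalling (5.6 ± 1.61 and 0.885 ± 0.516 RPKM), and 61211 bp from Cd83 (2.52 ± 1.61 and 0.285 ± 0.403 RPKM). A region within Cd274, which encodes the ligand PD-L1, and Plgrkt had 3.63 ± 2.33 and 0.425 ± 0.601 RPKM. Traf3, a restraint on B cell survival, had 1.29 ± 0.141 and 0.25 ± 0.17 RPKM, and Bcl3, a regulator of NF-kB, 1.79 ± 0.573 and 0.475 ± 0.375 RPKM (SD, n = 2 each). Whether any of these regions acts on the gene named was not tested.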
